A study of Mus musculus with 6 samples.

How the data were processed

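RNA from mouse small-intestinal organoids was sequenced on an Illumina NovaSeq instrument, in 3 libraries from organoids given arachidonic acid for 3 days before passaging and 3 from organoids given the vehicle, 0.1% ethanol, with RNA taken on day 3 after passaging. The deposited values were FPKM that the authors made by dividing each gene's fragments by its length and by the fragments assigned in the library, as inferred from the values, since the labels name no unit. HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used, per the submitters' processing notes, which give neither their roles nor their order. The genome build, the gene annotation and whether counting used strand are not given in the sources used here, so no coordinates are printed and overlapping, antisense and near-identical genes are uncertain.

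Each library listed the same 53953 rows, of which 53465 carried an Ensembl mouse gene identifier and 488 were unannotated models. A symbol was found for 53274 identifiers and a mean transcript length in the GENCODE annotation M21 for 53360. The unannotated rows, which held 0.102% to 0.140% of the FPKM of a library, were tested but not named. Low FPKM multiplied by gene length fell on whole multiples of 1 step per library, with 96.3% to 96.7% of the values under 100 fragments within 0.1 of a whole number. The fragments recovered this way summed to 98.3% to 98.5% of those the step implied, and the implied totals are taken as the depth, 35.6 to 50.8 M fragments per library. Counting error is one source of spread, and the replicates vary beyond it.

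The planned test depended on the unit, and its FPKM form was used. Values were taken as log2(FPKM + 1), genes with a mean of at least 1 FPKM over the 6 libraries were kept, and limma (version 3.58.1 in R 4.3.3) fitted the group with a trend between variance and mean. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Log2 fold changes are arachidonic acid minus vehicle and, with 1 added to the FPKM, understate the ratio of low values. The 26 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested against all other genes with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. A list is said to be called where camera passed at the preset correlation. The plan also held fry, which tests a list without the other genes, and its results are given with the other settings below. The rule named the 10 largest rises and falls among genes past the threshold, with groups that did not overlap and at least 5 FPKM in the higher group, the 3 smallest p-values in each direction, up to 4 members of each list with the smallest p, and 19 genes always. Genes outside it are said to be chosen after their values were seen. Some genes that the rule or the lists name, 1 of the 19 among them, are not reported here. The counts of list members are out of those tested, which were 15 of 31 interferon, 13 of 30 cytokine, 23 of 38 eicosanoid and 21 of 32 Wnt component genes and at least 70% of each other list with a set test. The scripts ran in R and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

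The same test was tried on simulated data made from the means of the vehicle libraries, with 12442 genes tested for arachidonic acid against vehicle. It recovered 68.0% of genes changed by 1 log2 unit in either direction and 88.0% and 89.4% of genes raised and lowered by 2 units, with 16 false calls among 170. Few genes were changed there and the noise was drawn for each gene on its own. In the data arachidonic acid replicate 1 lies apart over many genes, so these rates may not hold for them. The groups share replicate numbers, but the labels do not say that these pair the cultures, so the plan held no term for the number in the main test. Deviations from the group means correlated across genes at -0.0811, 0.210 and -0.0623 for the same numbers. For different numbers they correlated at -0.177 to 0.190. Genes are not independent replicates, so these values do not settle whether the numbers pair the cultures. The settings fixed beforehand were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, quantile normalization, rescaling to TPM, the replicate number as a block and each library left out in turn. Chosen after seeing the data were median-of-ratios scaling, limma-voom on recovered fragments, a covariate for the libraries numbered 2, both of these left out and, beside that, both numbered 1 or both numbered 3 left out.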

Results

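Small-intestinal organoids are crypt-derived epithelial cultures that keep stem cells and the differentiated cell types of the gut lining. Organoids from the proximal small intestine of wild-type C57BL/6 mice were grown in Matrigel at passage 3 to 5 and exposed to arachidonic acid, an omega-6 polyunsaturated fatty acid, for 3 days before passaging. Control organoids received the vehicle, 0.1% ethanol. Total RNA was taken on day 3 after passaging and sequenced from 3 libraries per group. The concentration of arachidonic acid is not given in the sources used here. Each library listed FPKM, fragments scaled by gene length and sequencing depth, for 53953 rows, and the values implied 37.4, 36.6 and 38.5 M fragments in the vehicle libraries and 50.8, 35.6 and 48.6 M in the arachidonic acid libraries (M, 1e+06). Nothing says whether the libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

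The first principal component of the tested genes held 85.2% of the variance and separated the groups. Vehicle libraries lay between -41.6 and -40.4, arachidonic acid replicates 2 and 3 at 58.1 and 54.6, and arachidonic acid replicate 1 at 10.2, between the vehicle libraries and its own group. For genes past the test with a difference of at least 0.5 log2 units, its position is given below. It is the fraction of the way, in FPKM, from the vehicle mean, at 0, to the mean of arachidonic acid replicates 2 and 3, at 1. These fractions are not on the log2 scale of the component and the fold changes, where they would differ. The median position was 0.56 over 3399 such genes. The test included replicate 1, so genes where it lay near or beyond the vehicle libraries were less likely to pass. The positions here and below are therefore selected in part by the values of replicate 1. Mitochondrially encoded transcripts took 3.49%, 4.17% and 3.18% of fragments in the vehicle libraries and 2.66%, 2.42% and 2.21% in the arachidonic acid libraries.

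**Figure D1:**
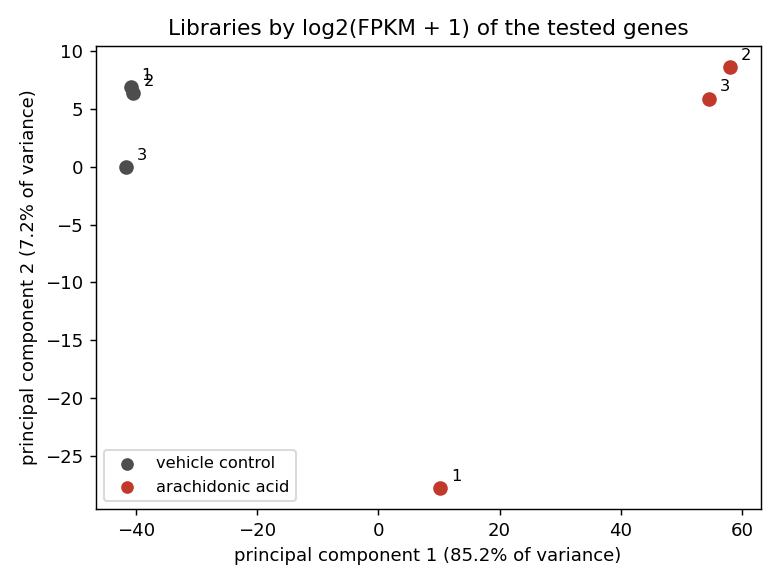
Principal components 1 and 2 of log2(FPKM + 1) over the 12913 tested genes, 1 point per library with its replicate number, vehicle in grey and arachidonic acid in red. The vehicle libraries lie together at the left, and arachidonic acid replicate 1 lies at 10.2 on component 1, away from replicates 2 and 3 at 58.1 and 54.6.

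The comparison of arachidonic acid with vehicle addresses how the fatty acid changes the organoid transcriptome, and, after the title of the series, its genes of intestinal regeneration and Wnt signalling. The 10 largest rises included Akr1b8, Msln, Ly6a, S100a6 and Aldh3a1. Akr1b8 (ENSMUSG00000029762), an aldo-keto reductase, rose from 1.34 ± 0.435 to 315 ± 139 FPKM (mean ± SD, n = 3 libraries per group here and below). Its log2 fold change, on the log2(FPKM + 1) scale as all folds here, was 6.97 (SE 0.37, adjusted p = 0.00027). Msln (ENSMUSG00000063011), which encodes mesothelin, rose from 2.65 ± 0.983 to 332 ± 149.6 FPKM. Ly6a (ENSMUSG00000075602), the stem cell antigen Sca-1, rose from 3.13 ± 1.23 to 270.4 ± 164 FPKM. S100a6 (ENSMUSG00000001025), a calcium-binding protein, rose from 11.7 ± 5.24 to 636 ± 249 FPKM. Aldh3a1 (ENSMUSG00000019102), an aldehyde dehydrogenase, was at 0.0204 FPKM in vehicle replicate 3, listed at 0 in the other vehicle libraries, and at 29.9, 246 and 312 FPKM with arachidonic acid. Its call (adjusted p = 0.0018) was lost with limma-voom on recovered fragments (adjusted p = 0.099).

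Among the 10 largest rises were also Prl2c3, Prl2c2, Syt8, Capg and Ly6d, with log2 fold changes of 5.98, 5.91, 5.82, 5.59 and 5.51. Prl2c2 and Prl2c3 are near-identical proliferin genes that can share reads, so their separate values are uncertain. The 10 largest falls included Olfm4, Pigr and Spink1. Olfm4 (ENSMUSG00000022026), a crypt stem cell marker, fell from 190.4 ± 41.4 to 14.7 ± 16.6 FPKM (log2 fold change -4.12, SE 0.67, adjusted p = 0.0049). Pigr (ENSMUSG00000026417), the receptor that carries immunoglobulin A across the epithelium, fell from 840.4 ± 80.7 to 87.9 ± 107 FPKM (log2 fold change -3.96, SE 0.77, adjusted p = 0.0085). Spink1 (ENSMUSG00000024503), a trypsin inhibitor, fell from 66.8 ± 11.1 to 4.62 ± 7.96 FPKM. Clca4b and Cyp2c68 had log2 fold changes of -4.52 and -3.80. The other 5 of the 10 largest falls were the pseudogenes Gm8979, Gm27149 and 9130208D14Rik, the provisional gene model Gm45912 and the transcribed pseudogene BC064078, at -4.89, -4.06, -4.03, -4.35 and -3.87, all uncertain where they share reads with a parent gene. BC064078 was called with all 6 libraries (adjusted p = 0.016) and without arachidonic acid replicate 1, and its adjusted p was 0.058, 0.056 and 0.056 without vehicle replicates 1, 2 and 3 and 0.0511 and 0.0523 without arachidonic acid replicates 2 and 3.

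The smallest p-values among the rises belonged to Prl2c3 (adjusted p = 2.7e-05), the gene 2210407C18Rik, which rose from 33.2 ± 4.64 to 379.5 ± 11.8 FPKM, and Aldh1a1, a retinaldehyde dehydrogenase, which rose from 47.0 ± 3.37 to 275 ± 22.5 FPKM (log2 fold change 2.52, SE 0.09, adjusted p = 5.6e-05). Among the falls they belonged to 3 gut hormone genes. Gcg, the glucagon and GLP-1 precursor, fell from 54.8 ± 3.13 to 12.9 ± 0.196 FPKM (log2 fold change -2.01, SE 0.07, adjusted p = 5.6e-05). Cck, cholecystokinin, fell from 187 ± 25.6 to 44.4 ± 4.27 FPKM. Gip, the incretin hormone, fell from 138 ± 24.1 to 15.4 ± 3.50 FPKM. In all, limma called 2690 genes higher and 2502 lower of 12913 tested at a Benjamini-Hochberg adjusted p under 0.05, of which 777 and 472 had an absolute log2 fold change of at least 1. The groups did not overlap for 55.0% of the tested genes, where chance gives 10% for 3 libraries against 3. Without arachidonic acid replicate 1 the counts were 3554 and 4192. They were 1724 and 1245 without vehicle replicate 1 and 1712 and 1364 without arachidonic acid replicate 3, and the lower genes numbered 1317, 1491 and 1453 without vehicle replicate 2, vehicle replicate 3 and arachidonic acid replicate 2.

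Wnt target genes, the readouts of beta-catenin and TCF transcription, moved in both directions. Of 19 tested members 9 rose, 3 fell and 7 did not pass (10 higher and 3 lower when adjusted over the list alone). Of the 19, 2 were under 1 FPKM with vehicle and tested only for their values with arachidonic acid. Ascl2 (ENSMUSG00000009248), a transcription factor of crypt stem cells, rose from 11.6 ± 1.71 to 36.6 ± 8.74 FPKM (log2 fold change 1.56, SE 0.19, adjusted p = 0.0022). Cd44 (ENSMUSG00000005087), a hyaluronan receptor, rose from 20.1 ± 1.10 to 65.0 ± 7.85 FPKM (log2 fold change 1.64, SE 0.10, adjusted p = 0.00041). Ccnd1, cyclin D1, rose from 15.8 ± 0.570 to 101 ± 34.3 FPKM (log2 fold change 2.54, SE 0.25, adjusted p = 0.0012). Ephb2, an ephrin receptor of the crypt base, rose from 40.4 ± 4.06 to 68.1 ± 6.49 FPKM. Axin2 (ENSMUSG00000000142), the most widely used Wnt reporter gene, did not pass, at 122 ± 9.39 and 126 ± 4.48 FPKM with vehicle and arachidonic acid (log2 fold change 0.05, SE 0.07, adjusted p = 0.63). Lgr5 (ENSMUSG00000020140), the R-spondin receptor of crypt stem cells, was at 78.8 ± 9.79 and 74.1 ± 6.73 FPKM (log2 fold change -0.09, SE 0.11, adjusted p = 0.55) and Sox9 at 29.2 ± 0.819 and 29.1 ± 1.54 FPKM (log2 fold change -0.01, SE 0.07, adjusted p = 0.94). Myc was at 50.2 ± 1.40 and 59.1 ± 5.36 FPKM (log2 fold change 0.23, SE 0.08, adjusted p = 0.057) and passed with TPM rescaling (adjusted p = 0.030), with median-of-ratios scaling (adjusted p = 0.023) and without arachidonic acid replicate 1 (log2 fold change 0.16, adjusted p = 0.042). Zfp703 fell from 127 ± 4.02 to 81.5 ± 6.58 FPKM (log2 fold change -0.64, SE 0.08, adjusted p = 0.0019). The other two that fell, named after their values were seen, were Cdx1, an intestinal homeobox gene, at -1.20 on the log2 scale, and Apcdd1, a Wnt inhibitor, at -0.61 (adjusted p = 0.042), whose call was lost with no filter on low values (adjusted p = 0.12) and without any 1 library but arachidonic acid replicate 1 (adjusted p = 0.081 to 0.14). The median log2 fold change of the list was 0.23 (camera adjusted p = 0.031, and adjusted p = 0.37 with an estimated correlation). Its call was also lost with no filter on low values (adjusted p = 0.062) and without vehicle replicate 2 (adjusted p = 0.0511), and the median position of arachidonic acid replicate 1 was 0.49.

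Of 21 Wnt ligands, receptors and pathway components 5 rose and 6 fell (5 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.82). The frizzled receptor genes Fzd2 and Fzd1 fell, Fzd2 from 5.46 ± 0.421 to 0.617 ± 0.333 FPKM and Fzd1 from 2.68 ± 0.198 to 0.599 ± 0.141 FPKM. Dvl2, a cytoplasmic transducer, fell from 24.9 ± 1.37 to 16.8 ± 0.640 FPKM. Lrp5, a Wnt co-receptor, rose from 23.4 ± 0.610 to 51.2 ± 12.1 FPKM. Crypt stem cell markers split likewise, with 8 higher and 10 lower of 24 (9 higher and 10 lower when adjusted over the list alone; camera adjusted p = 0.91). Some of these markers, Axin2, Ascl2, Lgr5, Cd44 and Sox9 among them, also stand in the list of Wnt targets, so the lists are not independent. Lrig1, a negative regulator of receptor tyrosine kinases, rose from 98.1 ± 2.08 to 148 ± 12.5 FPKM. Rgmb, a BMP co-receptor, fell from 76.6 ± 3.55 to 47.6 ± 3.73 FPKM, beside the rises of Ascl2 and Cd44 and the fall of Olfm4. The stem cell list had a median of 0.02 and a mean of -0.21, which differ in sign, and camera gave the direction up, and its median was -0.00098 without vehicle replicate 2. The component list had a median near 0 and a mean of -0.12. Leaving out any 1 library but arachidonic acid replicate 1 lowered these counts, to between 2 and 3 higher and 4 lower components, and to between 4 and 6 higher and 6 and 8 lower stem cell markers. In replicate 1 of arachidonic acid the members lay at a median position of 0.52 over the stem cell list and 0.72 over the component list.

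**Figure D2:**
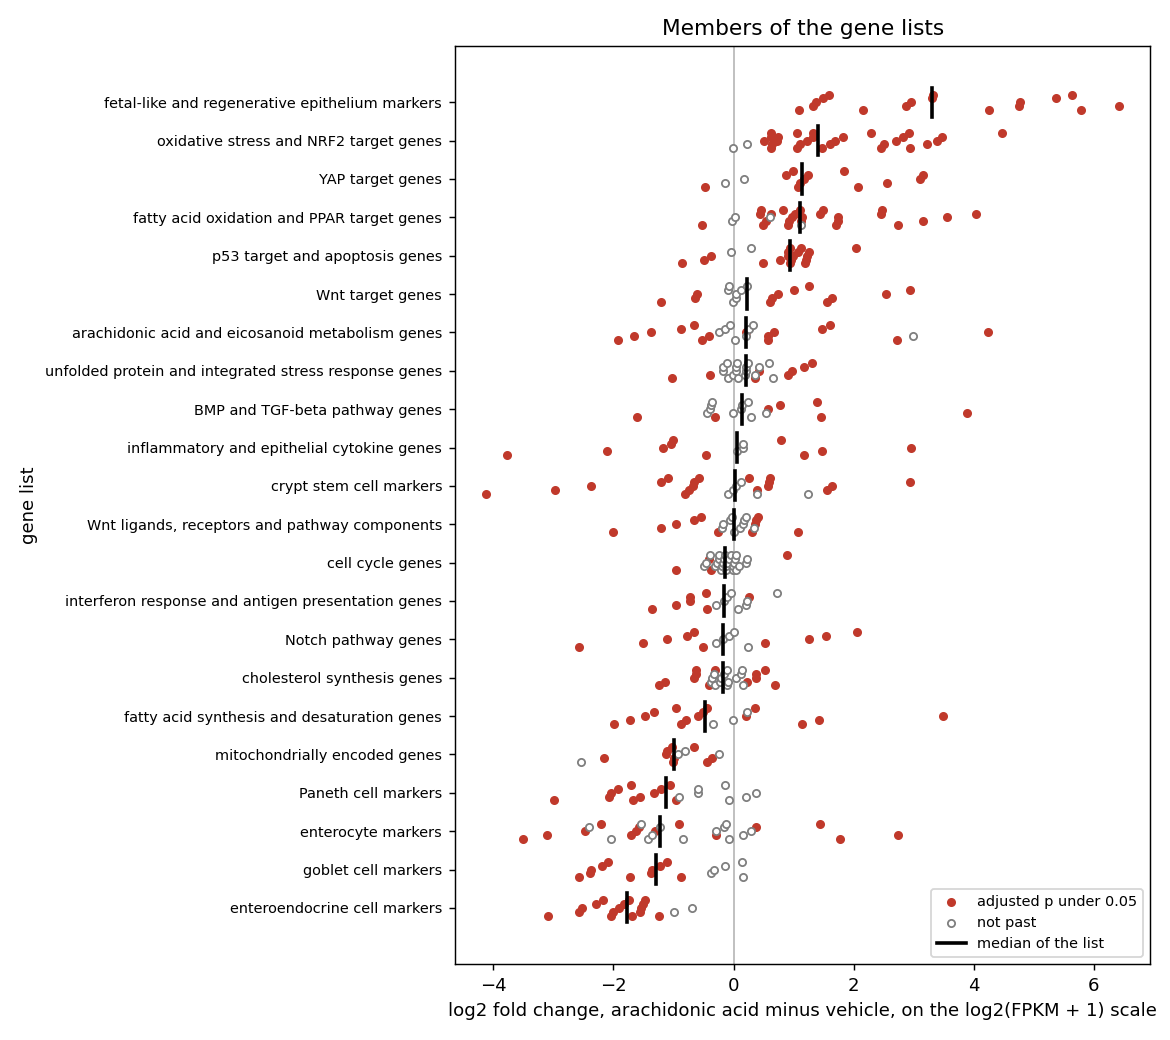
Log2 fold change on the log2(FPKM + 1) scale (x axis, arachidonic acid minus vehicle) of each tested member of the 22 gene lists with a set test (y axis), 1 point per gene, red where the adjusted p was under 0.05 and open otherwise, with a black bar at each list's median. The fetal-like list has the highest median, 3.31, and the enteroendocrine list the lowest, -1.78.

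All 17 markers of fetal-like and regenerative epithelium that were tested, of 20 in the list, rose (17 higher and 0 lower when adjusted over the list alone), with a median log2 fold change of 3.31. Of these, 3 were under 1 FPKM with vehicle and tested only for their values with arachidonic acid, so that their rises follow in part from the filter. The list included Ly6a, Msln and S100a6. Anxa10 rose from 2.26 ± 0.564 to 60.5 ± 5.92 FPKM (log2 fold change 4.25, SE 0.15, adjusted p = 5.6e-05) and Anxa1, an annexin that binds membrane phospholipids, rose from 7.82 ± 3.29 to 234 ± 65.4 FPKM (log2 fold change 4.75, SE 0.31, adjusted p = 0.00041). Il1rn, the interleukin 1 receptor antagonist, rose from 1.25 ± 0.391 to 64.1 ± 25.2 FPKM (log2 fold change 4.78, SE 0.31, adjusted p = 0.00041). Clu, clusterin, a marker of revival stem cells named here after its values were seen, rose from 4.08 ± 1.41 to 50.1 ± 18.3 FPKM. The list differed from the other genes (camera adjusted p = 9.3e-13), a call lost with an estimated correlation (adjusted p = 0.37 with an estimated correlation). Of 14 YAP target genes, which report the Hippo pathway, 11 rose and 1 fell (11 higher and 1 lower when adjusted over the list alone), with a median of 1.14 (camera adjusted p = 8.1e-05, and adjusted p = 0.37 with an estimated correlation). Tead4, a DNA-binding partner of YAP, rose from 0.135 ± 0.114 to 8.92 ± 2.31 FPKM (log2 fold change 3.10, SE 0.20, adjusted p = 0.00041). F3, tissue factor, rose from 3.08 ± 0.393 to 38.4 ± 18.4 FPKM. Ccn1 rose from 1.76 ± 0.148 to 5.57 ± 0.924 FPKM. Wwc1, an upstream Hippo regulator, rose from 46.8 ± 2.42 to 103 ± 7.23 FPKM. The gene that fell, Nuak2, named after its values were seen, had a log2 fold change of -0.48 (adjusted p = 0.038), a call lost with no filter on low values, with TPM rescaling and with the replicate block (adjusted p = 0.088, 0.0539 and 0.061), with both libraries numbered 2 left out (adjusted p = 0.22) and without any 1 library but arachidonic acid replicate 1 (adjusted p = 0.092 to 0.12). Of the 14 YAP targets 4 were likewise tested only for their values with arachidonic acid. The YAP call was lost with a minimum mean of 5 FPKM, which left 7 members (adjusted p = 0.063). Arachidonic acid replicate 1 took a median position of 0.50 over the fetal-like members and 0.47 over the YAP members, and without it the medians were 3.48 and 1.26.

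Genes of fatty acid oxidation and targets of the lipid-sensing PPAR receptors rose, 24 of 29, and 1 fell (26 higher and 1 lower when adjusted over the list alone). Of those tested, 4 were under 1 FPKM with vehicle and passed the filter only for their values with arachidonic acid. Cpt1a, which controls the entry of fatty acids into mitochondria, rose from 18.0 ± 2.01 to 52.3 ± 1.38 FPKM (log2 fold change 1.49, SE 0.09, adjusted p = 0.00041). Pdk4, a kinase that shuts off pyruvate dehydrogenase, rose from 0.783 ± 0.423 to 19.7 ± 4.41 FPKM (log2 fold change 3.55, SE 0.22, adjusted p = 0.00041). Eci2, an enoyl-CoA isomerase, rose from 54.8 ± 1.67 to 186 ± 16.5 FPKM. Vnn1, a pantetheinase, rose from 0.558 ± 0.124 to 25.3 ± 6.69 FPKM. The gene that fell was Acadm, the medium-chain acyl-CoA dehydrogenase, named after its values were seen, at -0.53 on the log2 scale (adjusted p = 0.014, and 0.056 and 0.0522 without vehicle replicates 2 and 3). The median of the list was 1.11 (camera adjusted p = 1.2e-12, and adjusted p = 0.37 with an estimated correlation). Replicate 1 of arachidonic acid lay at a median position of 1.22 here.

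Fatty acid synthesis and desaturation genes went both ways, 5 higher and 10 lower of 18 (6 higher and 11 lower when adjusted over the list alone), and the list was not called (camera adjusted p = 0.18). Both desaturase genes that make arachidonic acid from linoleic acid fell. Fads1 (ENSMUSG00000010663), the delta-5 desaturase, fell from 131 ± 6.79 to 34.2 ± 16.1 FPKM (log2 fold change -1.99, SE 0.28, adjusted p = 0.0031). Fads2 (ENSMUSG00000024665), the delta-6 desaturase, fell from 239 ± 16.3 to 90.2 ± 36.6 FPKM (log2 fold change -1.47, SE 0.25, adjusted p = 0.0057). Gpam and Aacs, both of lipid synthesis, fell from 17.7 ± 0.642 to 8.70 ± 1.44 FPKM and from 182 ± 3.66 to 105 ± 13.8 FPKM. Me1, malic enzyme, which supplies NADPH, rose from 10.8 ± 1.54 to 132 ± 17.4 FPKM (log2 fold change 3.49, SE 0.13, adjusted p = 8.2e-05). Acacb rose from 0.392 ± 0.0740 to 2.74 ± 0.480 FPKM. Cholesterol synthesis genes numbered 5 higher and 7 lower of 26 (5 higher and 8 lower when adjusted over the list alone; camera adjusted p = 0.29), among them Acat2, which fell from 106 ± 7.18 to 67.2 ± 8.05 FPKM, and Msmo1, which rose from 108 ± 4.07 to 140.3 ± 6.15 FPKM. Without arachidonic acid replicate 1, 14 cholesterol synthesis genes were lower, and its median position was 0.67 over the fatty acid synthesis list.

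Of 23 genes of arachidonic acid and eicosanoid metabolism 8 rose and 7 fell (9 higher and 7 lower when adjusted over the list alone; camera adjusted p = 0.37), and 5 were tested only for their values with arachidonic acid. Ptgs2 (ENSMUSG00000032487), cyclooxygenase 2, rose from 0.111 ± 0.116 to 7.01 ± 3.96 FPKM (log2 fold change 2.72, SE 0.37, adjusted p = 0.0028). Pla2g4a, the cytosolic phospholipase that releases arachidonic acid from membranes, rose from 15.3 ± 2.72 to 44.9 ± 11.5 FPKM (log2 fold change 1.48, SE 0.21, adjusted p = 0.0031). Ephx1, an epoxide hydrolase that also stands in the list of NRF2 targets, rose from 163 ± 11.8 to 506 ± 116 FPKM. Pla2g5, a secreted phospholipase, rose from 0.706 ± 0.443 to 45.4 ± 34.0 FPKM (log2 fold change 4.23, SE 0.84, adjusted p = 0.0093), a call lost with limma-voom on recovered fragments (adjusted p = 0.12). The counts of this list were between 4 and 6 higher and 0 and 3 lower without any 1 of the vehicle libraries or arachidonic acid replicates 2 and 3, and replicate 1 lay at a median position of 0.35.

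Oxidative stress genes and targets of the transcription factor NRF2 rose, 28 of 30, and none fell (29 higher and 0 lower when adjusted over the list alone), with a median of 1.40 (camera adjusted p = 1.2e-14, and adjusted p = 0.37 with an estimated correlation). Cbr3, a carbonyl reductase, rose from 55.5 ± 7.63 to 431 ± 94.0 FPKM (log2 fold change 2.92, SE 0.18, adjusted p = 0.00041), and the glutathione transferase genes Gsta2 and Gsta3 rose from 20.4 ± 2.53 to 245 ± 79.7 FPKM and from 54.7 ± 5.31 to 401 ± 111 FPKM. Gsta genes resemble one another and can share reads, so their separate values are uncertain. G6pdx, the first enzyme of the pentose phosphate pathway, rose from 56.4 ± 3.30 to 143 ± 17.2 FPKM (log2 fold change 1.32, SE 0.10, adjusted p = 0.00057). Slc7a11, the cystine importer, rose from 6.54 ± 1.15 to 182 ± 84.4 FPKM. Hmox1, haem oxygenase 1, rose from 3.04 ± 0.543 to 48.2 ± 27.2 FPKM. These genes, and Gpx1 and Sod2, were named after their values were seen. Gpx1 and Sod2 did not pass (adjusted p = 0.071 and 0.88), and Gpx1 passed with TPM rescaling and without arachidonic acid replicate 1 (adjusted p = 0.032 and 0.026). Of 20 p53 target and apoptosis genes 15 rose and 3 fell (15 higher and 3 lower when adjusted over the list alone), with a median of 0.94 (camera adjusted p = 8.1e-05, and adjusted p = 0.37 with an estimated correlation). Mdm2, which degrades p53, rose from 30.2 ± 1.38 to 68.0 ± 12.5 FPKM (log2 fold change 1.13, SE 0.14, adjusted p = 0.0021). Ccng1 rose from 89.8 ± 3.45 to 213 ± 40.1 FPKM. Zmat3 rose from 15.8 ± 0.293 to 39.6 ± 8.02 FPKM, and the death receptor gene Eda2r rose from 6.56 ± 0.463 to 16.5 ± 1.20 FPKM. One of the 3 that fell was Sesn1, at -0.85 on the log2 scale, named after its values were seen. In replicate 1 of arachidonic acid the members lay at a median position of 0.55 over the NRF2 list and 0.53 over the p53 list.

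Unfolded protein and integrated stress response genes were 6 higher and 2 lower of 25 (6 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.18). Xbp1 fell from 209 ± 14.0 to 159 ± 1.23 FPKM. Ern2, a goblet cell stress sensor, fell from 4.24 ± 0.863 to 1.59 ± 0.520 FPKM. Dnajb9, a chaperone, rose from 12.5 ± 0.633 to 17.1 ± 0.913 FPKM. Without arachidonic acid replicate 1 the counts were 13 higher and 4 lower and the list was called (median 0.24, adjusted p = 0.016, and adjusted p = 0.41 with an estimated correlation), whereas 1 to 3 were higher without any other 1 library.

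Markers of enteroendocrine, goblet and Paneth cells fell. Of 18 enteroendocrine markers 16 fell and none rose (0 higher and 16 lower when adjusted over the list alone), with a median of -1.78 (camera adjusted p = 5.7e-11, and adjusted p = 0.37 with an estimated correlation). Of the 18, 3 were under 1 FPKM with arachidonic acid and tested only for their vehicle values, so the count of falls follows in part from the filter. The markers that fell included Gcg, Cck and Gip. Chgb, a granin of hormone granules, fell from 208 ± 14.3 to 42.2 ± 10.3 FPKM (log2 fold change -2.29, SE 0.16, adjusted p = 0.00049) and Chga (ENSMUSG00000021194) fell from 73.9 ± 7.80 to 15.8 ± 3.77 FPKM (log2 fold change -2.18, SE 0.16, adjusted p = 0.00058). The other two, Sst and Reg4, named after their values were seen, did not pass (adjusted p = 0.10 and 0.099), and Reg4 passed without arachidonic acid replicate 1 (adjusted p = 1.9e-05). Arachidonic acid replicate 1 took a median position of 0.94 for this list. Of 16 goblet markers 11 fell and none rose (0 higher and 11 lower when adjusted over the list alone), with a median of -1.29 (camera adjusted p = 8.1e-05, and adjusted p = 0.37 with an estimated correlation). Of the 16, 2 were likewise tested only for their vehicle values. Tff3, a trefoil peptide of mucus, fell from 580.0 ± 71.1 to 223 ± 28.3 FPKM (log2 fold change -1.37, SE 0.13, adjusted p = 0.0010). Spink4 fell from 863 ± 140.1 to 175 ± 80.3 FPKM. Guca2a, guanylin, fell from 47.3 ± 6.25 to 17.7 ± 2.27 FPKM. Ccl9 fell from 5.26 ± 1.65 to 0.469 ± 0.416 FPKM. Muc2, the main gut mucin, was below the filter, at 1.15, 2.45 and 0.424 FPKM with vehicle, at 0.629 and 0.385 FPKM in arachidonic acid replicates 1 and 3, and listed at 0 in replicate 2.

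Of 18 Paneth markers 11 fell and none rose (0 higher and 12 lower when adjusted over the list alone), with a median of -1.13 (camera adjusted p = 0.00092, and adjusted p = 0.37 with an estimated correlation). The alpha-defensin genes Defa24 and Defa17, antimicrobial peptides, fell from 1276 ± 307 to 301 ± 64.6 FPKM and from 216 ± 27.1 to 30.3 ± 20.2 FPKM, although reads of near-identical defensin genes cannot be assigned with certainty. Ang4, an antimicrobial ribonuclease, fell from 60.6 ± 15.2 to 19.7 ± 4.10 FPKM (log2 fold change -1.56, SE 0.23, adjusted p = 0.0034). Kit, a receptor tyrosine kinase, fell from 6.38 ± 0.845 to 2.25 ± 0.840 FPKM. Lyz1 (ENSMUSG00000069515), lysozyme, fell from 200.2 ± 45.6 to 70.4 ± 51.9 FPKM (log2 fold change -1.70, SE 0.46, adjusted p = 0.026). That call was lost with no filter on low values (adjusted p = 0.071), and without vehicle replicates 1, 2 and 3 and arachidonic acid replicates 2 and 3 (adjusted p = 0.095, 0.077, 0.0547, 0.074 and 0.084). The number of lower Paneth markers was 5, 6, 7 and 6 without vehicle replicates 1 and 2 and arachidonic acid replicates 2 and 3. Replicate 1 of arachidonic acid lay at a median position of 0.68 over the Paneth list and 0.69 over the goblet list.

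Absorptive enterocyte markers went both ways. Of 27 tested, 4 rose and 10 fell (4 higher and 15 lower when adjusted over the list alone). Lct, lactase, fell from 9.14 ± 1.85 to 0.176 ± 0.256 FPKM (log2 fold change -3.11, SE 0.20, adjusted p = 0.00041). Alpi (ENSMUSG00000079440), intestinal alkaline phosphatase, rose from 26.1 ± 3.78 to 92.2 ± 20.5 FPKM (log2 fold change 1.76, SE 0.18, adjusted p = 0.0013). Fabp1, a fatty acid-binding protein, rose from 354 ± 51.2 to 2565 ± 1337 FPKM (log2 fold change 2.74, SE 0.33, adjusted p = 0.0021). Creb3l3, a transcription factor of lipid metabolism, rose from 36.8 ± 5.56 to 106 ± 41.0 FPKM. Fabp1 and Creb3l3 also stand in the list of PPAR targets. The median was -1.23 (camera adjusted p = 0.0478, and adjusted p = 0.74 with an estimated correlation). Leaving out vehicle replicate 2 or 3 or arachidonic acid replicate 2 or 3 ended the call (camera adjusted p = 0.11, 0.0513, 0.0536 and 0.13), and the number of lower genes was 6, 2 and 3 without vehicle replicates 1, 2 and 3 and 18, 6 and 5 without arachidonic acid replicates 1, 2 and 3. The call was also lost with a pseudocount of 0.1, a minimum mean of 5 FPKM, quantile normalization, limma-voom, a covariate for the libraries numbered 2, both of those left out and both numbered 3 left out (highest camera adjusted p = 0.12, and the lowest just above the threshold), and arachidonic acid replicate 1 lay at a median position of 0.57.

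Of 20 tuft cell markers 4 were tested and none passed, with adjusted p-values of 0.060 for Il17rb, 0.062 for Avil, 0.093 for Cd24a and 0.19 for Ltc4s. Without arachidonic acid replicate 1, Il17rb and Avil passed (adjusted p = 0.00089 and 9.1e-05), and Il17rb passed with TPM rescaling (adjusted p = 0.0479). Dclk1, the usual tuft marker, was at 0.183, 0.148 and 0.206 FPKM with vehicle, at 0.0112 and 0.0059 FPKM in arachidonic acid replicates 1 and 3, and listed at 0 in replicate 2. Markers of cells that a crypt preparation can carry over were low. Of 15 fibroblast markers 1, Vim, reached the filter, and it fell from 4.77 ± 0.795 to 0.817 ± 0.566 FPKM (log2 fold change -1.70, SE 0.23, adjusted p = 0.0030). Of 15 immune markers Cd68 and Laptm5 reached it. Cd68, a lysosomal protein of macrophages, rose from 1.90 ± 0.323 to 14.7 ± 10.4 FPKM (log2 fold change 2.13, SE 0.59, adjusted p = 0.028), a call lost with no filter on low values, with limma-voom and without any 1 library but arachidonic acid replicate 1 (adjusted p = 0.076, 0.093 and 0.074 to 0.090). Laptm5 was at 0.811 ± 0.482 and 2.28 ± 1.24 FPKM (adjusted p = 0.11, and 0.0026 without arachidonic acid replicate 1). None of 10 endothelial markers reached the filter, and the highest single value among them was 0.425 FPKM.

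**Figure D3:**
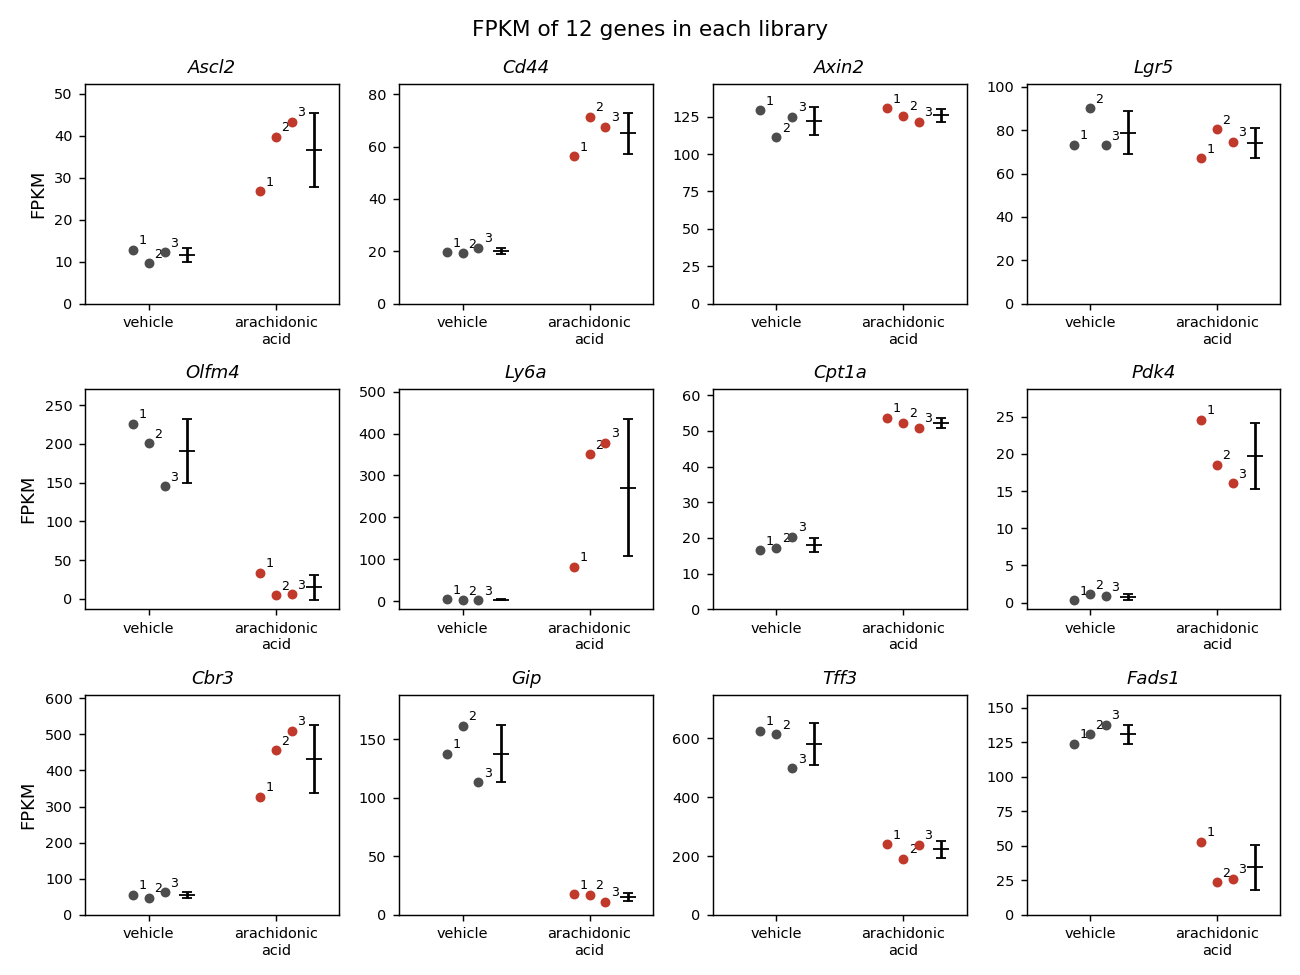
FPKM (y axis, linear) of 12 genes in each library, vehicle in grey and arachidonic acid in red, points numbered by replicate, with the group mean and SD of 3 libraries as a black bar beside them. Axin2 and Lgr5 overlap between the groups, and the other 10 genes do not, with Ascl2 at 11.6 against 36.6 FPKM and Olfm4 at 190.4 against 14.7 FPKM on average.

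Cell cycle genes were not called as a list. Of 30, 1 rose and 3 fell (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.18), and Mki67 (ENSMUSG00000031004), the proliferation marker, was at 73.8 ± 6.13 and 66.8 ± 17.2 FPKM (log2 fold change -0.17, SE 0.17, adjusted p = 0.46). The arachidonic acid libraries differed in direction for Mki67. Replicate 1, at 86.6 FPKM, lay above the vehicle libraries at 67.5 to 79.8 FPKM. Replicates 2 and 3, at 54.9 and 59.0 FPKM, lay below them. Rrm2, a ribonucleotide reductase subunit, rose from 81.6 ± 7.82 to 152 ± 18.8 FPKM. Hmgb2, a chromatin protein, fell from 431 ± 17.9 to 227 ± 64.4 FPKM. Ube2c and Tk1 fell by 0.40 and 0.38 on the log2 scale (adjusted p = 0.030 and 0.032), and both calls were lost with no filter on low values and without any 1 library but arachidonic acid replicate 1 (adjusted p = 0.057 to 0.10). Without arachidonic acid replicate 1, 18 cell cycle genes fell (1 without any other 1 library), the list was called (median -0.31, adjusted p = 0.0023, and adjusted p = 0.61 with an estimated correlation) and Mki67 passed (log2 fold change -0.36, adjusted p = 0.0049).

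Notch pathway genes were 4 higher and 6 lower of 15 (4 higher and 7 lower when adjusted over the list alone; camera adjusted p = 0.60). The ligand gene Jag1 rose from 6.56 ± 0.372 to 17.5 ± 4.39 FPKM and the receptor gene Notch3 rose from 0.221 ± 0.0474 to 4.51 ± 2.33 FPKM, while Notch1, a receptor of crypt cells, fell from 52.4 ± 2.63 to 30.6 ± 6.21 FPKM. BMP and TGF-beta pathway genes were 5 higher and 2 lower of 17 (5 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.37). Bmp8b, a BMP ligand, rose from 0.243 ± 0.120 to 19.7 ± 10.4 FPKM. Tgfbr2 rose from 24.4 ± 2.24 to 66.6 ± 12.7 FPKM. Smad6, an inhibitory SMAD, fell from 2.33 ± 0.381 to 0.0935 ± 0.0811 FPKM. Interferon response and antigen presentation genes were 1 higher and 6 lower of 15 (2 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.18), with H2-K1, a class I histocompatibility gene, lower (from 832 ± 30.9 to 603 ± 27.8 FPKM), as were B2m (from 274 ± 5.94 to 168 ± 37.6 FPKM) and Psmb9 (from 6.14 ± 0.385 to 1.84 ± 0.821 FPKM). The 1 that was higher, H2-D1, also a class I gene and named after its values were seen, had a log2 fold change of 0.27 (adjusted p = 0.018), a call lost with both libraries numbered 2 left out (adjusted p = 0.18) and without any 1 library but arachidonic acid replicate 1 (adjusted p = 0.057 to 0.077). Inflammatory and epithelial cytokine genes were 4 higher and 6 lower of 13 (4 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.91). Cxcl16 rose from 1.72 ± 0.384 to 6.53 ± 0.252 FPKM. Il33, an alarmin that also stands in the fetal-like list, rose from 0.0342 ± 0.0424 to 7.48 ± 3.32 FPKM. Reg3b, an antimicrobial lectin, fell from 22.0 ± 5.46 to 1.06 ± 1.77 FPKM. The cytokine list had a median of 0.05 and a mean of -0.22, which differ in sign, and camera gave the direction up. Its median was -0.10 and -0.04 without arachidonic acid replicates 1 and 2. Lower Notch genes numbered 1 to 3 without any 1 library but arachidonic acid replicate 1, and lower cytokine genes 2 or 3. BMP and TGF-beta genes were 3 higher and 1 lower without vehicle replicate 1 and 7 and 6 without arachidonic acid replicate 1.

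Of the 13 protein genes of the mitochondrial genome 9 fell and none rose (0 higher and 11 lower when adjusted over the list alone), with a median of -0.998 (camera adjusted p = 8.1e-05, and adjusted p = 0.37 with an estimated correlation). mt-Cytb, cytochrome b, fell from 4927 ± 518 to 2314 ± 505 FPKM (log2 fold change -1.11, SE 0.16, adjusted p = 0.0037). mt-Nd2 fell from 2534 ± 336 to 1258 ± 301 FPKM. mt-Co3 fell from 68.3 ± 5.87 to 31.0 ± 5.92 FPKM and mt-Atp6 fell from 159 ± 56.8 to 33.5 ± 3.63 FPKM. The 4 that did not pass, named after their values were seen, were mt-Co1, mt-Co2, mt-Nd3 and mt-Nd4l (adjusted p = 0.16, 0.14, 0.057 and 0.060), of which mt-Nd3 and mt-Nd4l passed without arachidonic acid replicate 1 (adjusted p = 5.1e-07 and 0.0039), mt-Nd3 with limma-voom (adjusted p = 0.037) and mt-Nd4l with quantile normalization (adjusted p = 0.0484). mt-Nd4l overlaps mt-Nd4 and mt-Atp6 overlaps mt-Atp8, so their reads cannot be told apart with certainty. In replicate 1 of arachidonic acid the members lay at a median position of 0.71. With both libraries numbered 2 left out, a setting chosen after seeing the data, 635 genes were higher and 219 lower over the transcriptome, and 43 of 115 named genes past the test lost their call, Olfm4, Ephb2, Ptgs2, Fads2, mt-Cytb and mt-Nd2 among them. Their log2 fold changes were 0.77 to 1.10 times as large as with all libraries (median 0.88), and leaving out both libraries numbered 3, also 2 per group and chosen after seeing the data, gave 390 higher and 140 lower. Without the number 3, 58 of the 115 named genes lost their call, Ascl2, Fads1, Ccn1, Mdm2 and Rrm2 among them, and without both numbered 1 it was 0.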

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

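Median-of-ratios scaling, limma-voom on recovered fragments, the covariate for the libraries numbered 2 and leaving out both libraries of 1 number were chosen after seeing the data. The planned count models were not run. The planned list test fry gave adjusted p = 0.0084 for Wnt components and for interferon genes, 0.015 for crypt stem cell markers and 0.046 for eicosanoid genes. Camera had called none of these lists. For the enterocyte list, which camera called, fry gave adjusted p = 0.25. The other lists that camera called passed with fry. Over all settings, log2 fold changes of the named genes kept their direction and side of the threshold in 2067 comparisons, lost their call in 137, gained one in 12 and changed sign in 9. List medians kept both in 358, their lists lost a call in 15 and gained one in 5, and 18 medians changed sign. All these sign changes were of genes and lists with no call under either setting. The median of Wnt pathway components went from 0.00111 to -0.00778 with a pseudocount of 0.1, -0.0232 with quantile normalization, -0.0282 with limma-voom and -0.0216 with both libraries numbered 2 left out. That of crypt stem cell markers went from 0.0205 to -0.0225 with quantile normalization and -0.0310 with both of these left out, and that of cytokine genes from 0.0508 to -0.20 with a minimum mean of 5 FPKM and -0.0844 with both left out. Eicosanoid genes went from 0.20 to -0.0140 with a minimum mean of 5 FPKM and BMP and TGF-beta genes from 0.13 to -0.00744 with no filter. Axin2 was at -0.00233 with quantile normalization and -0.0146 with both libraries numbered 2 left out, and Sox9 at 0.0509 with TPM and 0.0139 with median-of-ratios scaling. Without each library in turn, the values that changed sign ran from -0.0266 to 0.13 for Wnt components, -0.000978 to 0.0537 for stem cell markers, -0.10 to 0.12 for cytokine genes, -0.0154 to 0.0917 for Axin2, -0.15 to 0.0135 for Lgr5 and -0.0326 to 0.0362 for Sox9. The enterocyte call was lost with a pseudocount of 0.1 (median -1.23), a minimum mean of 5 FPKM (-1.23), quantile normalization (-1.28), limma-voom on recovered fragments (-1.22) and replicate 2 as a covariate (-1.23). The Wnt target call was lost with no filter (0.0479), where low genes joined the list, and the YAP call with a minimum mean of 5 FPKM (1.07), which left fewer members. With both libraries numbered 2 left out, 635 genes were higher and 219 lower, and the Wnt target and enterocyte calls were lost (medians 0.26 and -0.95). With both numbered 3 left out, 390 were higher and 140 lower, the enterocyte call was lost (median -0.77), and Wnt components were at -0.0457 and Sox9 at 0.0554. With both numbered 1 left out, 3402 were higher and 3844 lower, the cell cycle, cholesterol synthesis and unfolded protein lists gained a call (medians -0.35, -0.28 and 0.30) that none held with an estimated correlation (adjusted p = 0.65, 0.47 and 0.47), and cytokine genes were at -0.0167. Without each library in turn, 1712 to 3554 genes were higher and 1245 to 4192 lower, and medians ran from 0.18 to 0.27 for Wnt targets, -0.31 to -0.0460 for the cell cycle, -1.55 to -0.81 for enterocytes and 0.0772 to 0.25 for the unfolded protein list. Among the settings that left out libraries, more genes were called only where arachidonic acid replicate 1 was among those left out. On the log2 scale it correlated with replicates 2 and 3 at 0.964 and 0.968, against 0.994 between these. It thus widened the spread within its group, and the calls lost without other libraries are not independent of one another. The cause of each change of a list or gene was not tested. Among genes named after their values were seen, leaving out both libraries numbered 2 ended the calls of Cdx1, Apcdd1, Nuak2, Acadm, Sesn1, H2-D1, Serpinf2, Otc and Oat (adjusted p = 0.064 to 0.22). With the replicate block, 2263 genes were higher and 1998 lower. Rescaling to TPM gave 3156 higher and 2099 lower genes and quantile normalization 2409 and 2969, so the balance of rises and falls rests on the scaling. The depth behind the values was 35.6 to 50.8 M fragments.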

Other observations

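Every test in this part but the thinning of fragments and the nuclear oxidative phosphorylation genes was chosen only after the result was seen, and so were the 7 gene lists and the genes named here. Members with a mean under 1 FPKM over the 6 libraries were not tested. Of 22 basement membrane genes 12 were tested and 10 rose (10 higher and 0 lower when adjusted over the list alone), with a median log2 fold change of 1.95 (camera adjusted p = 2.9e-06, and adjusted p = 0.20 with an estimated correlation). Col4a1 and Col4a2, the main type IV collagen chains, rose from 0.195 ± 0.149 to 26.5 ± 8.88 FPKM and from 0.256 ± 0.146 to 29.9 ± 12.3 FPKM, and the laminin gene Lama5 rose from 2.59 ± 0.755 to 53.2 ± 26.5 FPKM. Of the 12, 4 were under 1 FPKM with vehicle and tested only for their values with arachidonic acid, Col4a1 and Col4a2 among them. Of 28 genes of squamous epithelium 9 were tested and rose (9 higher and 0 lower when adjusted over the list alone; camera adjusted p = 3.3e-06, and adjusted p = 0.20 with an estimated correlation), among them Krt4, a keratin, from 0.00406 ± 0.00702 to 20.1 ± 12.0 FPKM, and Sprr2a1, from 5.48 ± 1.86 to 179 ± 84.1 FPKM, which shares reads with near-identical copies. Of these 9, 6 were under 1 FPKM with vehicle and tested only for their values with arachidonic acid, so that all 9 rose follows in part from the filter. The other 19 had a mean under 1 FPKM. Of 17 gastric epithelium genes 6 were tested and 4 rose (5 higher and 0 lower when adjusted over the list alone; camera adjusted p = 0.00017, and adjusted p = 0.20 with an estimated correlation), with Vsig1 from 0.109 ± 0.0719 to 7.61 ± 0.642 FPKM and Psca from 0.237 ± 0.0588 to 10.8 ± 4.64 FPKM. Of these 6, 4 were under 1 FPKM with vehicle, and the 11 not tested had a mean under 1 FPKM. Anxa10 and Ly6d, named above, belong to the gastric and squamous lists.

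Of 10 genes of the plasminogen system 6 were tested, 5 rose and Serpinf2 fell (5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0055, and adjusted p = 0.20 with an estimated correlation), with Plaur, the urokinase receptor, from 1.80 ± 0.372 to 59.4 ± 20.4 FPKM and Plat, the tissue activator, from 0.467 ± 0.228 to 22.8 ± 9.89 FPKM. Of the 6, 2 were under 1 FPKM with vehicle, Plat among them, and 1 with arachidonic acid. Of 13 AP-1 family genes 10 were tested and 8 rose (8 higher and 0 lower when adjusted over the list alone; camera adjusted p = 0.00047, and adjusted p = 0.18 with an estimated correlation), with Junb from 44.4 ± 7.71 to 121 ± 25.5 FPKM and Fos from 3.77 ± 0.707 to 16.7 ± 3.98 FPKM. Urea cycle and proline metabolism genes were 8 lower and 2 higher of 13 tested from 15 (2 higher and 8 lower when adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.20 with an estimated correlation), with Otc, ornithine transcarbamylase, from 39.8 ± 3.00 to 4.78 ± 5.94 FPKM and Oat from 1263 ± 108 to 344 ± 257 FPKM, and 5, 6, 5, 9, 7 and 6 were lower without vehicle replicates 1, 2 and 3 and arachidonic acid replicates 1, 2 and 3. In the same order 1, 1, 1, 3, 1 and 1 were higher, and 1 was with quantile normalization and with median-of-ratios scaling. Retinoid metabolism genes were 5 higher and 4 lower of 13 tested from 23 (6 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.62, and adjusted p = 0.78 with an estimated correlation), with a median of -0.49 where camera gave the direction up. Of these, 1 was lower without each vehicle library and without arachidonic acid replicate 2, 2 without replicate 3 and 7 without replicate 1, and 3, 4, 3, 6, 4 and 3 were higher without vehicle replicates 1, 2 and 3 and arachidonic acid replicates 1, 2 and 3. Cytosolic ribosomal protein genes were 63 lower and 2 higher of 91, with a median of -0.38. With quantile normalization 43 were lower and 3 higher, with a median of -0.23. Xist was at or below 0.0744 FPKM and Ddx3y between 18.7 and 22.9 FPKM in the 6 libraries.

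The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 5192 genes past the threshold and the highest of the others 0 with limma, where 33 to 775 genes had an unadjusted p under 0.05 against 6593. Every other split puts vehicle and arachidonic acid libraries in the same group, so their difference widens the spread within groups. Few calls were assured there, and the contrast decides nothing. The number of splits with as many genes, the real one included, was 1.

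Arachidonic acid replicate 1 lay between the vehicle libraries and replicates 2 and 3, at 52.6% of the way on the first principal component. Thinning it to 70.1% of its fragments moved it by -0.2% of the gap, which argues against depth. Vehicle RNA or cells mixed into it would put all changed genes at 1 shared fraction below 1, but PPAR list members lay at a median of 1.22 (95% bootstrap interval 0.941 to 1.44) and fetal-like members at 0.501 (0.440 to 0.664). Enteroendocrine members, also picked after their values were seen, lay at a median of 0.943 (quartiles 0.880 to 0.967 over 16 genes). Lists at such different fractions argue against a mixture as the whole of the pattern, for the genes of these lists. The interval of the PPAR list reaches below 1 and the lists were picked for their differences. A mixture may therefore remain as part of the pattern and cannot be told apart from a weaker response of most lists. Over the 3399 genes with a position 248 lay above 1, with 14 of 22 PPAR members and 1 of 17 fetal-like members. Neither a mixture nor a uniformly weaker response alone gives a position above 1 beyond the noise. All these genes were called with replicate 1 in the fit, so they were selected in part by its values. No biological explanation was tested, since the design holds no group for it.

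Both libraries numbered 2 had little of a few transcripts. Gm23935 was at 84.0 and 64.1 FPKM in vehicle and arachidonic acid replicate 2, against 10389 and 9469 FPKM in the other vehicle libraries and 8466 and 7129 FPKM in the other arachidonic acid libraries. A term for the number 2 called 4 genes, Gm23935 and Gm24270, annotated as miRNA, CT010467.1, annotated as rRNA, and the protein-coding Lars2, and terms for 1 and 3 called 0. Such a term sets 2 libraries against 4, so few calls cannot show that a library batch is limited to few genes. With that term in the fit, 89.3% of the 5192 calls were kept, but each group holds 1 library numbered 2, so the term leaves every fold change as it was and this share says nothing of the batch. With both of these libraries left out, 848 of 5158 calls were kept, at 2 libraries per group, with all 5158 in the same direction and log2 fold changes at a median of 0.92 times those with all libraries. Leaving out both libraries numbered 3 kept 526 of 5177 calls, and leaving out both numbered 1 kept 5001 of 5179, so the calls lost without the number 2 do not speak for a batch. No biological explanation was tested, as the labels do not say what the replicate numbers stand for.

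Mitochondrially encoded transcripts were lower with arachidonic acid, at a median log2 fold change of -0.998 over 13 genes. With quantile normalization, the scaling that moved it most, the median was -0.817, with 8 genes lower against 9, and with TPM and median-of-ratios scaling it was -0.939 and -0.976, with 7 and 8 lower. The median of all tested genes was -0.0289. The medians under these scalings argue against scaling between libraries as the whole of the fall. Within the libraries numbered 1 and 3 the median of the 13 genes was -0.823, with -1.37 between the libraries numbered 2, 1 against 1. The fall was thus also seen without the libraries numbered 2, although 2 of the 13 genes were then called, as without both numbered 3. An equal shift of both libraries numbered 2 cannot set the groups apart, so these values do not decide on a batch. The larger fall between them leaves a part of theirs open. The 77 nuclear-encoded oxidative phosphorylation genes had a median of -0.177 (95% bootstrap interval over the genes -0.252 to -0.139), with 26 called lower and 1 higher. That interval measures the spread between genes and not between libraries, so it excludes nothing about the treatment. In these libraries the median fall of the nuclear-encoded genes was smaller than that of the mitochondrial transcripts, and a smaller general fall stays open. A change in mitochondrial number or transcription with the treatment may lie behind the pattern and was not tested.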
